A study of Homo sapiens with 41 samples.

How the data were processed

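The samples were 41 hybridisations of 2-colour spotted cDNA arrays, on which a Cy5-labelled sample and a Cy3-labelled reference compete for the same spots. The labels gave 12 tissue arrays, 9 cell line arrays, 11 arrays of laser-captured prostate cells, 3 arrays of formalin-fixed paraffin-embedded (FFPE) prostate and 6 arrays with the same benign prostate pool in both channels. Most samples had passed through whole transcriptome amplification (WTA), in which cDNA is multiplied by rounds of PCR before labelling.

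The values used were log ratios as deposited, taken as log2, in a pair of tables that the authors had already normalized. Background correction, within-array normalization, spot filtering and the log base were not given in the sources used here. One tissue value of -8.06 rules out a base of 10 in the tissue table, and the other table was taken to be on the same scale. The probe filter is unrecorded, and each array listed only part of its probes, so a missing value says nothing about a level. Direction was taken from the labels, which state Cy5 for the sample and Cy3 for the reference on every array, so positive values are likely higher in the sample. No dye swap was described.

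Array medians showed that values were close to centred as deposited. They were -0.0066, -0.0022, -0.017 and 0.0062 for unamplified tissue arrays 1, 2, 3 and 5, and 0.023 for unamplified tissue array 4. Amplified tissue gave 0.0063 at 12.5 ng, 0.018 at 25 ng, 0.00086 at 75 ng, -0.0039 at 150 ng and -0.0039, -0.011 and -0.0050 at 300 ng. Cell line medians were 0.0028 without amplification, 0.0088 at 1 ng, 0.010 and 0.0090 at 10 ng with 1 and 2 PCR rounds, 0.010 and 0.00081 at 25 ng with 1 and 2 rounds, 0.0042 and 0.0043 after 5 and 15 min of degradation and 0.0039 at 100 pg. Captured benign epithelium gave -0.00071, -0.0029, 0.0023, 0.013 and 0.0036, captured cancer 0.0018, -0.00028, 0.0046 and 0.0013, and captured stroma 0.019 and 0.0060. The FFPE medians were 0.0028 for benign tissue and 0.0065 and 0.0032 for cancer. The pool arrays gave 0.0015, 0.043, 0.127 and 0.090 for 1 to 4 rounds on both sides, 0.0094 for 2 against 4 rounds and 0.0016 for the array re-amplified from the first round. Scale and centring of the deposited values are otherwise unknown. Each array was centred on its own median before any test.

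Probes were named from the platform annotation, with symbols updated through gene identifiers of the GRCh38.p14 RefSeq gene table, from which no coordinates were used. The tissue table held 20000 probes, of which 12553 had 1 symbol, 939 several and 6508 none. The other table held 13185, 1037 and 5778. Identifiers matched for 12521 and 13174 single-symbol probes, and 21 and 11 symbols were updated. No gene was named from a probe with several symbols. Probes of one gene were averaged per array, and probes with no or several symbols were kept as their own features. Of the named results with several tested probes, 15 in all, 0 had probes of opposite sign, but many were named for a large difference or small p, which favours agreement. Over all genes with several tested probes, signs were opposite for 231 of 514 at 300 ng and 275 of 622 over all inputs. They were opposite for 119 of 291 in captured cancer, 59 of 192 in stroma and 93 of 248 in FFPE. Changed probes had opposite signs for 1, 16, 2, 0 and 0 genes, so averaging can hide disagreement. No pair of arrays held identical values at most of the shared probes.

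Differences were tested on the log2 scale with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment at 0.05, and every adjusted p below is limma's unless camera is named. A feature needed at least 3 values in each of the groups contrasted, 5 over the amplified arrays of all inputs, 6 for the input trend, 2 in stroma and every FFPE value. The stroma and cancer contrasts came from one fit over the 11 captured arrays, and the FFPE contrast from one over 14 arrays, where the single benign FFPE array was assumed to vary like the other groups. Tissue array 4, whose labels give an amplified reference, stayed out. Gene lists were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation, over lists with at least 5 measured members. Cell line and pool arrays had 1 array per protocol and were not tested. There, list medians were placed among 10000 random lists of the same size. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the rest.

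Groups, tests, gene lists, the naming rule and most of the other settings tried were fixed before the data were examined. The rule took 21 prostate genes wherever they were measured, the 10 highest and 10 lowest changed genes per comparison, and up to 4 members with the smallest p from each list described. In the cell line, genes had to be at least 2-fold changed without amplification and of the same sign on at least 7 of 8 amplified arrays. Which lists to describe, and which of their members beyond the strongest, was settled after the values were seen. The scaling of arrays to one spread was run with the median absolute value, which that limma method uses. Alternatives also covered centring, filters on missing values, single probes, array weights, robust eBayes, the replicate number as a block and leaving out each array. Removal of an amplification profile and restriction to features near 0 were added after seeing the data.

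The procedure was tested on simulated data with 200 features changed by known amounts. At differences of 0.5 and 1 log2, it recovered 42% and 92% of changed features for unamplified against 300 ng tissue, 30% and 94% over all inputs, 68% and 96% for captured cancer against benign, 64% and 96% for stroma and 60% and 98% for FFPE. For the trend, where the size is the change over the whole input range, it recovered 4% and 74%. In the group comparisons the simulated noise was the SD of residuals about group means, with no correction for the means fitted. Single-array groups add nothing to it, so it was smaller than the real spread, most of all for 300 ng tissue. Recoveries other than those of the trend are therefore likely too high. The number of arrays limits the precision. Tissue and cell line arrays repeat the same RNA pair, so their spread is that between labelings, amplifications and hybridisations. The labels do not tie captured regions to donors.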

Results

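Expression was measured as the log ratio of a sample over a reference on 41 arrays, in a study of whole transcriptome amplification (WTA) for expression profiling. Prostate tissue was represented by 12 arrays of one RNA pair, a localized prostate adenocarcinoma against a commercial pool of benign prostate RNA. Of these, 4 arrays held unamplified RNA, 7 held RNA amplified from 12.5, 25, 75, 150 or 300 ng (3 arrays at 300 ng, 1 at each other amount), and 1 held unamplified tumour against an amplified reference. LNCaP cells, an androgen-responsive prostate cancer line, were treated with 1 nM of the synthetic androgen R1881 for 24 h or with ethanol, and gave 9 arrays. Laser capture microdissection (LCM) gave 5 arrays of benign epithelium, 4 of cancerous epithelium and 2 of benign stroma next to cancer. FFPE tissue gave 1 benign and 2 cancer arrays, and 6 arrays held the benign pool in both channels. For captured arrays the labels gave 2 PCR rounds for the reference and no number for the captured sample. For FFPE arrays they gave 2 on both sides. Tissue arrays listed 9371 to 9856 probes, cell line arrays 8018 to 9701, pool arrays 9488 to 9992, captured arrays 4287 to 4933 and FFPE arrays 4829 to 4869. The SD of the log2 ratios within an array was 0.520 to 0.892 for tissue, 0.173 to 0.378 for the cell line, 0.356 to 0.533 for captured cells and 0.359 to 0.440 for FFPE.

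The first comparison asked which tumour-to-benign ratios changed when 300 ng of tissue RNA was amplified. Several ratios that were high in unamplified tumour fell, among them those of genes of white blood cells. LAPTM5, a lysosomal membrane protein of leukocytes, went from 2.31 ± 0.31 (SD, n = 4) to 0.57 ± 0.14 (n = 3), a difference of -1.74 (adjusted p = 0.000828), and LYZ, lysozyme, from 1.39 ± 0.24 to -0.07 ± 0.03 (-1.47, adjusted p = 0.00104). FGF12, a fibroblast growth factor homologue, fell by 1.84 ± 0.16 (SE; adjusted p = 0.000367), from 2.88 ± 0.16 to 1.04 ± 0.13. Several ratios that were low in the tumour rose. MYH11, the smooth muscle myosin heavy chain, went from -2.53 ± 0.61 to -0.45 ± 0.30 (2.08 ± 0.29 SE, adjusted p = 0.00352), and MET, the hepatocyte growth factor receptor, from -1.39 ± 0.20 to 0.41 ± 0.39 (1.80, adjusted p = 0.000878).

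Of 5208 features, 315 changed, 123 upward and 192 downward, and 113 of them by at least 1 log2. All 31 changed genes named here had every 300 ng array beyond every unamplified array that listed them. Many genes here and below were named for a large difference or a small p, which favours such separation. The strongest other falls were in LUC7L3 (-1.60), a splicing factor, CLEC3A (-1.53), a C-type lectin, HLA-DQA1 (-1.41), a class II antigen-presenting chain whose close paralogs make its value uncertain, MARCHF7 (-1.38), a ubiquitin ligase, FOXF2 (-1.36), a forkhead transcription factor, PNN (-1.36) and AMACR (-1.34), a racemase used as a prostate cancer marker, whose ratio was 3.87 ± 0.58 without amplification and 2.53 ± 0.45 with it. The strongest other rises were in NDE1 (2.68), ADIRF (2.35), NBL1 (2.02), MYL9 (1.96), a myosin light chain, EFNB2 (1.80), AOC1 (1.77), EML2 (1.76) and ICAM5 (1.57). NDE1 overlaps MYH11 and ADIRF overlaps AGAP11 in the GRCh38.p14 gene table, so their values are uncertain. GSTP1, a glutathione transferase silenced in most prostate cancers, rose by 1.11 (SE 0.18, adjusted p = 0.00717). GOLM1 (-0.51, adjusted p = 0.163), HPN (-0.49, adjusted p = 0.0916), ERG (0.46, adjusted p = 0.13) and ACTA2 (-0.01, adjusted p = 0.989) did not pass.

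By list, 5 of 15 leukocyte genes fell and 1 rose (9 and 1 when adjusted over the list alone), including KIT (-1.22), a mast cell receptor, and CD68 (-0.94). The list's median was -0.62, with a camera adjusted p of 0.000472 that was lost with an estimated correlation (adjusted p = 0.191 with an estimated correlation). Basal epithelial genes rose in 3 of 6 cases (4 over the list alone), with SNAI2 at 0.72 and CAV1 at 0.71, a median of 0.71 and a camera adjusted p of 0.00094. Of 20 genes known to be lower in prostate cancer 4 rose (5 over the list alone), with NELL2 at 1.24 and GSTM3 at 0.67 (median 0.48, camera adjusted p = 0.000472). Both calls were kept with an estimated correlation (0.00377 and 0.0411), but 4 of the 6 basal genes tested are also among these 20, so the calls are not separate. Smooth muscle genes rose in 3 of 10 cases (4 over the list alone), with MYLK at 0.97 and a median of 0.74 (camera adjusted p = 0.000816, adjusted p = 0.189 with an estimated correlation). Cytosolic ribosomal protein genes fell in 3 of 24 cases (6 over the list alone), RPS3A (-0.95), RPS25 (-0.93) and RPL31 (-0.65), with a median of -0.26 (camera adjusted p = 0.000816, adjusted p = 0.597 with an estimated correlation). Ribosomal protein genes have many processed pseudogenes, so single members are uncertain. Of 20 genes of folding and transport in the endoplasmic reticulum 0 passed limma over all features and 10 fell over the list alone, with 1245 features in all under an unadjusted p of 0.05 (median -0.37, camera adjusted p = 0.000472, adjusted p = 0.237 with an estimated correlation).

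Amplified ratios lay nearer to 0 than unamplified ones for 268 of the 315 changed features and for 3351 of all 5208 tested, and 90 of the 315 had the opposite sign. Scaling all arrays to one spread left 310 changed features, 164 of them shared with the 315, and ended the list calls for basal (median 0.34, adjusted p = 0.0794), ribosomal (-0.22, 0.101), leukocyte (-0.36, 0.117), smooth muscle (0.13, 0.412) and lower-in-cancer genes (0.06, 0.543). It also ended the calls of AMACR (-0.24, adjusted p = 0.565), CAV1 (0.52, 0.0577), CD68 (-0.62, 0.0730), GSTM3 (0.29, 0.292), MYLK (0.32, 0.296), RPL31 (-0.51, 0.0531) and SNAI2 (0.32, 0.287). The p-values measure only spread between labelings, amplifications and hybridisations of one RNA pair. The count was 129 without unamplified array 2, and 52, 68 and 33 without 300 ng arrays 1, 2 and 3. Of the 31 named changed genes 15 kept their call whichever array was left out. Those that lost it had their highest adjusted p without 300 ng array 1 for SNAI2 (0.69, adjusted p = 0.169), FOXF2 (-1.23, 0.112), RPS3A (-0.84, 0.0986) and GSTP1 (0.95, 0.0547), and without array 2 for CAV1 (0.65, 0.153) and NELL2 (1.01, 0.0669). For the others it was highest without array 3, namely GSTM3 (0.57, adjusted p = 0.209), RPL31 (-0.61, 0.157), AMACR (-1.26, 0.129), CD68 (-0.93, 0.123), MYLK (0.86, 0.114), RPS25 (-0.91, 0.112), EFNB2 (1.72, 0.0734), CLEC3A (-1.45, 0.0691), MARCHF7 (-1.38, 0.0576) and MYL9 (2.07, 0.0529). Tested probe by probe, KIT (-0.63, adjusted p = 0.0532), PNN (-0.87, 0.0611), CAV1 (0.71, 0.110), GSTM3 (0.67, 0.103) and RPL31 (-0.30, 0.305) did not pass. With array 4 among the unamplified arrays 216 features changed, and AMACR (-1.18, adjusted p = 0.0555), RPS3A (-0.82, 0.0504), RPS25 (-0.52, 0.499), RPL31 (-0.58, 0.0694) and SNAI2 (0.66, 0.0607) were not among them. With no filter on missing values SNAI2 (adjusted p = 0.0516) and GSTM3 (0.0588) did not pass.

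**Figure D1:**
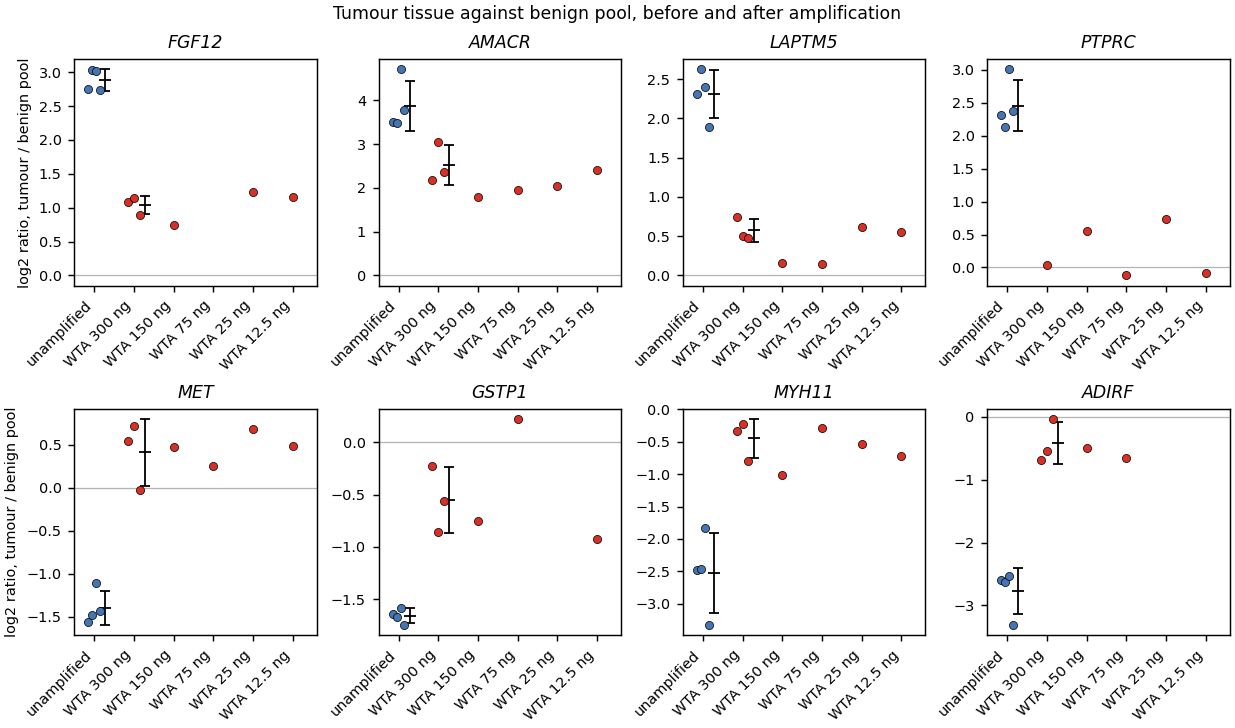
Log2 ratio of tumour over benign pool (vertical axis) for FGF12, AMACR, LAPTM5, PTPRC, MET, GSTP1, MYH11 and ADIRF in unamplified arrays and arrays amplified from 300, 150, 75, 25 and 12.5 ng (horizontal axis). Points are arrays and bars show the mean ± SD. MYH11 lies at -2.53 on average without amplification and at -0.45 after amplification from 300 ng.

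The second comparison set the unamplified arrays against all 7 amplified arrays, whatever their input, and shares its arrays with the first, so it is not independent of it. The leukocyte tyrosine phosphatase PTPRC (CD45) fell by 2.23 ± 0.21 (SE, adjusted p = 9.99e-06) from an unamplified ratio of 2.45 ± 0.38, and LAPTM5 (-1.85), KIT (-1.11) and LYZ (-1.33, adjusted p = 1.18e-05) fell too. SIRT4, a mitochondrial sirtuin, rose by 2.82 ± 0.28 (adjusted p = 1.2e-05), and ANGPT2, an angiopoietin, by 1.55 (adjusted p = 8.34e-05). Of the contractile genes, MYH11 rose by 1.97 (adjusted p = 1.69e-05), MYL9 by 1.86, MYLK by 1.17 and ACTN1 by 0.84. AMACR fell by 1.61 ± 0.24 (adjusted p = 0.000211).

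Of 5806 features, 1429 changed, 504 upward and 925 downward. The strongest falls also held CTNNAL1 (-2.22), FGF12 (-1.84), LUC7L3 (-1.68), TOP2B (-1.59), a DNA topoisomerase, CLEC3A (-1.57), CAND1 (-1.52) and SMC3 (-1.52), a cohesin subunit, and the strongest rises NDE1 (2.66), ADIRF (2.29), NBL1 (1.90), AOC1 (1.87), MET (1.84) and EML2 (1.71). Leukocyte genes fell in 12 of 18 cases and rose in 1, the same counts as when adjusted over the list alone (median -0.70, camera adjusted p = 3.34e-05, adjusted p = 0.0564 with an estimated correlation). Basal genes rose in 4 of 6 cases (5 over the list alone; median 0.60, camera adjusted p = 0.00129) and smooth muscle genes in 5 of 11 (5 over the list alone; median 0.65, camera adjusted p = 3.59e-05), calls kept with an estimated correlation (0.0118 and 0.0349). Genes known to be lower in prostate cancer, which include 4 of the 6 basal ones, rose in 10 of 20 cases (11 up and 1 down over the list alone), among them GSTP1 (1.14) and NELL2 (1.08), with a median of 0.47 (camera adjusted p = 3.59e-05, adjusted p = 0.0564 with an estimated correlation). Endoplasmic reticulum genes fell in 11 of 21 cases (14 over the list alone), with the chaperone HSP90B1 at -1.44 (adjusted p = 0.00309), TRAM1 at -0.71, PDIA3 at -0.56 and SSR3 at -0.55 (median -0.38, camera adjusted p = 0.000194, adjusted p = 0.181 with an estimated correlation). Ribosomal protein genes fell in 10 of 25 cases (11 over the list alone), with RPS3A at -0.995, RPS25 at -0.92, RPL6 at -0.68 and RPL31 at -0.64 (median -0.35, camera adjusted p = 0.000232, adjusted p = 0.42 with an estimated correlation). GOLM1 (-0.72, adjusted p = 0.00514) and HPN (-0.53, 0.0043) fell and the fatty acid synthase FASN (0.63, 0.0113) rose, while ERG (0.38, 0.111) and ACTA2 (0.27, 0.316) did not pass.

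Of 37 named changed genes 35 had every amplified array beyond every unamplified one, counting only arrays that listed the gene, and GOLM1 and TRAM1 had 6 of 7. PTPRC, SIRT4, ADIRF, FASN and ACTN1 were listed on 5 of the 7 amplified arrays. The p-values again cover technical spread alone. After scaling to one spread the calls ended for AMACR (-0.55, adjusted p = 0.0872), FASN (0.31, 0.125), GOLM1 (-0.26, 0.241), HPN (-0.27, 0.121), HSP90B1 (-0.74, 0.0611) and RPL6 (-0.34, 0.0986), and for the basal (0.24, 0.0527), smooth muscle (0.08, 0.0592) and lower-in-cancer lists (0.11, 0.342). With array 4 among the unamplified arrays RPS25 (-0.51, adjusted p = 0.227) did not pass, and probe by probe neither PDIA3 (-0.53, 0.0534) nor RPL31 (-0.28, 0.107) did.

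Along the input amounts, from 12.5 to 300 ng, no gene's ratio passed the test of a trend. TPD52, a tumour protein often gained in prostate cancer, had a slope of 0.28 ± 0.06 (SE) per doubling of input, ABCC4, a drug transporter, 0.15 ± 0.04 and SPARCL1, a matrix protein, 0.15 ± 0.04, all with an adjusted p of 0.213. Slopes were 0.05 ± 0.07 for AMACR, 0.03 ± 0.05 for MYH11, -0.01 ± 0.04 for HPN, 0.06 ± 0.05 for GOLM1, 0.04 ± 0.08 for GSTP1, -0.13 ± 0.05 for ACTA2 and 0.10 ± 0.04 for ERG. limma called 0 of 6798 features, with 740 under an unadjusted p of 0.05. A change below 1 log2 over the whole range was often missed on simulated data.

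Each amplified tissue array was also set against the mean of the 4 unamplified arrays. Across features, which are not independent replicates, Pearson's r was 0.773 at 12.5 ng, 0.802 at 25 ng, 0.761 at 75 ng, 0.755 at 150 ng and 0.814, 0.806 and 0.777 at 300 ng. Of features at least 2-fold changed without amplification, 96.1 to 98.3% kept their direction and 27.5 to 45.6% were also at least 2-fold changed. An unamplified array set against the other 3 gave r between 0.805 and 0.907, with 57.2 to 76.8% also at least 2-fold changed. The slope of amplified on unamplified ratios was 0.64 for the 300 ng mean and 0.60 for the mean of all inputs.

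In LNCaP cells, several genes had high or low ratios of treated over control. Some were named for extreme ratios on the unamplified array and a shared sign on amplified ones, so their values do not test an androgen response. In the unamplified array MAOA, a monoamine oxidase, stood at 1.53, SYT1, a synaptotagmin, at 1.39 and ODC1, which makes putrescine at the head of polyamine synthesis, at 1.17. The 8 amplified arrays all had positive values for these genes, with medians of 0.84, 0.69 and 0.88. On the other side were the metalloproteinase MMP16 at -1.77 (amplified median -0.92, from -1.4998 to -0.36, 8 of 8 negative), LINC00839 at -1.12, FOLH1, the prostate-specific membrane antigen, at -0.77 (amplified median -0.40) and CAMK2N1, a kinase inhibitor, at -0.75 (amplified median -0.59). There was 1 array per protocol, so these are values without a test.

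Of 5804 named genes on the unamplified array 16 were at least 2-fold higher and 5 at least 2-fold lower. On all 9 arrays 2834 named genes were listed, and 9 higher and 2 lower ones met the rule for naming. They included SNAP25 (1.15, amplified median 0.22), MCCC2 (1.14, 0.51), WWC1 (1.14, 0.23) and SMS (1.11, 0.50), the spermine synthase. The androgen-induced list had a median of 0.45, above 0 in 26 of 28 members, at percentile 100 of random lists, whose medians lay between -0.08 and 0.09. Its members included SNAI2 (1.43, amplified median 0.47, 7 of 7 positive), STEAP4 (1.30, 0.45, 5 of 5), STK39 (1.28, 0.60, 7 of 7) and LRIG1 (1.19, 0.68, 7 of 7), and its amplified medians were 0.21 to 0.32. The androgen-repressed list had a median of -0.52 over 9 members, 4 of which were above 0, at percentile 0. It held the DOPA decarboxylase DDC (-1.11, amplified median -0.86, 7 of 7 negative) and the chemokine receptor ACKR3 (-1.04, -0.52, 7 of 7), and its amplified medians ran from -0.51 to -0.08, at percentiles of 0 to 19.7. Polyamine genes had a median of 0.20 over 7 members at percentile 98.7, with SRM at 0.30 and OAZ1 at 0.20, the latter positive on 3 of 8 amplified arrays. FASN stood at 0.85 (amplified 0.27 to 0.73), although its sterol and fatty acid list had a median of -0.09 at percentile 4.54. Values near 0 were seen for AMACR (0.15), HPN (0.15), GOLM1 (0.14), ERG (0.17), EZH2 (-0.03), ACTA2 (-0.01) and MYH11 (-0.06).

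Across features, r with the unamplified array was 0.369 at 100 pg, 0.431 at 1 ng, 0.541 and 0.502 at 10 ng with 1 and 2 rounds of PCR, 0.457 and 0.561 at 25 ng with 1 and 2 rounds, and 0.525 and 0.460 after 5 and 15 min of degradation. Slopes were 0.37 to 0.55. Between 97.2 and 100% of the 36 to 42 features at least 2-fold changed without amplification kept their direction, and 4.88 to 35% were also at least 2-fold changed. The 28 pairs of amplified arrays had r between 0.282 and 0.669. For 25 ng with 2 rounds, the labels of one array differ on the number of rounds.

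**Figure D2:**
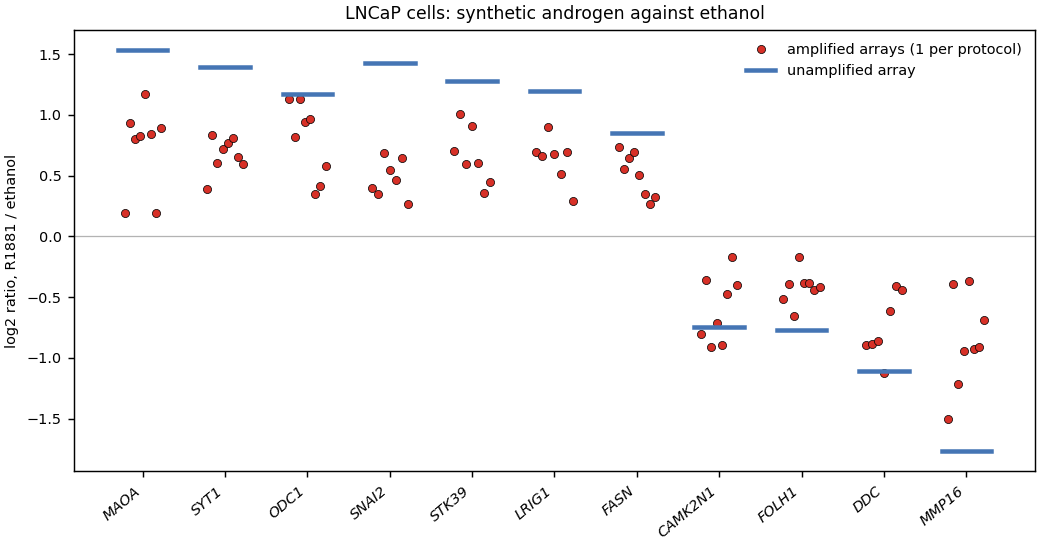
Log2 ratio of androgen-treated over ethanol-treated LNCaP cells (axis of values) for 11 genes, with the unamplified array as a blue bar and each amplified array as a red point. MAOA, at 1.53 without amplification, and MMP16, at -1.77, had amplified arrays on the same side of 0.

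The benign pool was hybridised against itself after different numbers of PCR rounds, with 1 array each. The SD of log2 ratios was 0.094 after 1 round on both sides, 0.142 after 2, 0.248 after 3 and 0.289 after 4, with 0, 1, 6 and 67 features beyond 2-fold of 8446, 8648, 8273 and 8398. The counts for 3 and 4 rounds moved with the processing, to 20 and 92 with values as deposited and to 0 and 5 of the 4522 features on all 6 pool arrays. It was 0.278 for 2 against 4 rounds, with 27 of 8576 features beyond 2-fold, and 0.108 for an array re-amplified from the first round, with 0 of 8449. Across features the arrays with 3 and 4 rounds correlated at 0.519, and the array re-amplified from the first round correlated at -0.466 with captured benign array 4 and at -0.434 with captured stroma array 1. Correlations below -0.3 between pool and captured arrays ran from -0.466 to -0.301. The dyes are stated and the pool arrays hold no contrast of samples, so directions were kept. The SDs and the counts beyond 2-fold do not depend on direction. The correlations here and the slopes on the profile of 2 against 4 rounds, given below, keep the sign as deposited.

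In captured cells the cancerous epithelium was compared with benign epithelium. MYO6, an unconventional myosin, rose by 1.26 ± 0.15 (SE, adjusted p = 0.000487). It went from -0.11 ± 0.12 (SD, n = 4, as benign array 1 did not list it) in benign to 1.15 ± 0.29 (n = 4) in cancer. HPN, the serine protease hepsin known to be high in prostate cancer, rose from 0.34 ± 0.17 to 0.79 ± 0.20 (0.45, adjusted p = 0.0301). ENG, endoglin, a TGF-beta co-receptor, fell from 1.33 ± 0.55 to -0.49 ± 0.22 (-1.82 ± 0.23, adjusted p = 0.000487), and MME, the membrane peptidase neprilysin, by 1.41 (adjusted p = 0.00684). RPS13, a ribosomal protein, rose by 0.98 (adjusted p = 0.000564), from -1.04 ± 0.14 to -0.06 ± 0.22, and UQCRB, a subunit of respiratory complex III, by 0.82 (adjusted p = 0.00127).

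Of 3031 features, 463 changed, 175 upward and 288 downward, and 14 of them by at least 1 log2. Of 38 named changed genes 35 had every cancer array beyond every benign array, counting only arrays that listed the gene, and MME, KRT8 and COX7C had 3 of 4. Other strong falls were in TGFB3 (-1.41), NIPAL3 (-1.27), the phospholipid-binding ANXA1 (-1.24), CD38 (-1.21), AZGP1 (-1.11), HSPA1L (-0.99), uncertain because of close paralogs, RBM47 (-0.96), EML2 (-0.95) and SLC14A1 (-0.90), a urea transporter. Other strong rises were in CCNG2 (0.96), PDHX (0.94), FNIP2 (0.92), UBE2E3 (0.89), UGDH (0.89), HINT1 (0.87), RPL30 (0.86) and the kinesin KIF5C (0.85). Ribosomal protein genes rose in 10 of 19 cases (13 when adjusted over the list alone), with RPL5 (0.73), RPL6 (0.72) and RPL22L1 (0.70) among them, a median of 0.52 and a camera adjusted p of 3.34e-07 (adjusted p = 0.233 with an estimated correlation). Oxidative phosphorylation genes rose in 9 of 31 cases (10 over the list alone), with UQCRC2 at 0.80, COX7C at 0.64 and ATP5PF at 0.53 (median 0.23, camera adjusted p = 0.000293, adjusted p = 0.367 with an estimated correlation). Sterol and fatty acid synthesis genes fell in 3 of 8 cases (7 over the list alone), the desaturase SCD (-0.80), the isomerase EBP (-0.79) and the transcription factor SREBF2 (-0.71), with a median of -0.46 (camera adjusted p = 0.000748, adjusted p = 0.237 with an estimated correlation). Genes known to be lower in prostate cancer fell in 5 of 15 cases (7 over the list alone; median -0.43, camera adjusted p = 0.000748, adjusted p = 0.115 with an estimated correlation), and CAV1 (-0.50) was one of them. Luminal genes fell in 3 of 5 cases (3 over the list alone), among them DPP4 (-0.75) and the keratin KRT8 (-0.69), with a median of -0.69 (camera adjusted p = 0.0205, adjusted p = 0.106 with an estimated correlation). Smooth muscle genes fell in 3 of 7 cases (5 over the list alone), ACTN1 (-0.60), ACTG2 (-0.59), which is close to ACTA2 in sequence, and CNN1 (-0.48), with a median of -0.42 (camera adjusted p = 0.0192, adjusted p = 0.367 with an estimated correlation). GSTP1 (-0.62, adjusted p = 0.0564), MYH11 (-0.42, 0.0819), FASN (-0.40, 0.145), ACTA2 (-0.33, 0.128) and GOLM1 (-0.21, 0.599) did not pass.

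Captured regions that share a donor would make these p-values too small, and the labels do not tie regions to donors. The count was 281 without cancer array 2. CAV1 lost its call without benign array 3 (-0.46, adjusted p = 0.0671) or 4 (-0.41, 0.0574) and without cancer array 1 (-0.51, 0.0503) or 3 (-0.41, 0.0843), and HPN without benign array 4 (0.41, 0.0591) or 5 (0.45, 0.0567) and cancer array 3 (0.45, 0.0577) or 4 (0.36, 0.0914). KRT8 lost it without benign array 2 (-0.63, adjusted p = 0.0529) and without cancer array 3 (-0.59, 0.0690) or 4 (-0.56, 0.0670), and ACTG2 without cancer array 3 (-0.52, 0.0538). Without cancer array 3 the luminal list (-0.59, adjusted p = 0.0585) and the smooth muscle list (-0.31, 0.0585) were not called, nor was the latter without benign array 1 (-0.33, 0.0866). Array weights ended the calls of HPN (0.36, adjusted p = 0.0521) and KRT8 (-0.51, 0.0539), and UQCRC2 (0.63, 0.0606) did not pass probe by probe. The profile of the pool array of 2 against 4 rounds moved with histology, with slopes of -0.36 ± 0.16 (SD) over the 5 benign arrays and 0.12 ± 0.09 over the 4 cancer arrays (exact two-sided permutation p = 0.00794). Pool arrays with equal rounds on both sides also had positive slopes on it, from 0.039 to 0.191. Without a dye swap, the profile may therefore not reflect rounds of PCR alone. With that profile removed, chosen after seeing the data, 352 features changed, and the calls ended for the oxidative phosphorylation list (-0.02, adjusted p = 0.0681), the smooth muscle list (-0.39, 0.0681) and the genes ACTG2 (-0.39, 0.119), ACTN1 (-0.33, 0.144), ATP5PF (0.36, 0.0738), COX7C (0.44, 0.0564), HINT1 (0.41, 0.0502), HSPA1L (-0.73, 0.0525), KIF5C (0.59, 0.0584), KRT8 (-0.46, 0.145), RPL5 (0.43, 0.0613), SLC14A1 (-0.78, 0.0573) and UBE2E3 (0.57, 0.0690). Removal left 76 higher and 276 lower features. Among features within 0.3 of 0 in the stroma comparison, also chosen after seeing the data, the ribosomal (0.15, adjusted p = 0.140) and lower-in-cancer lists (-0.55, 0.140) were not called, but that comparison includes the cancer arrays, so genes are removed by their own change and the lost calls say nothing about stroma.

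**Figure D3:**
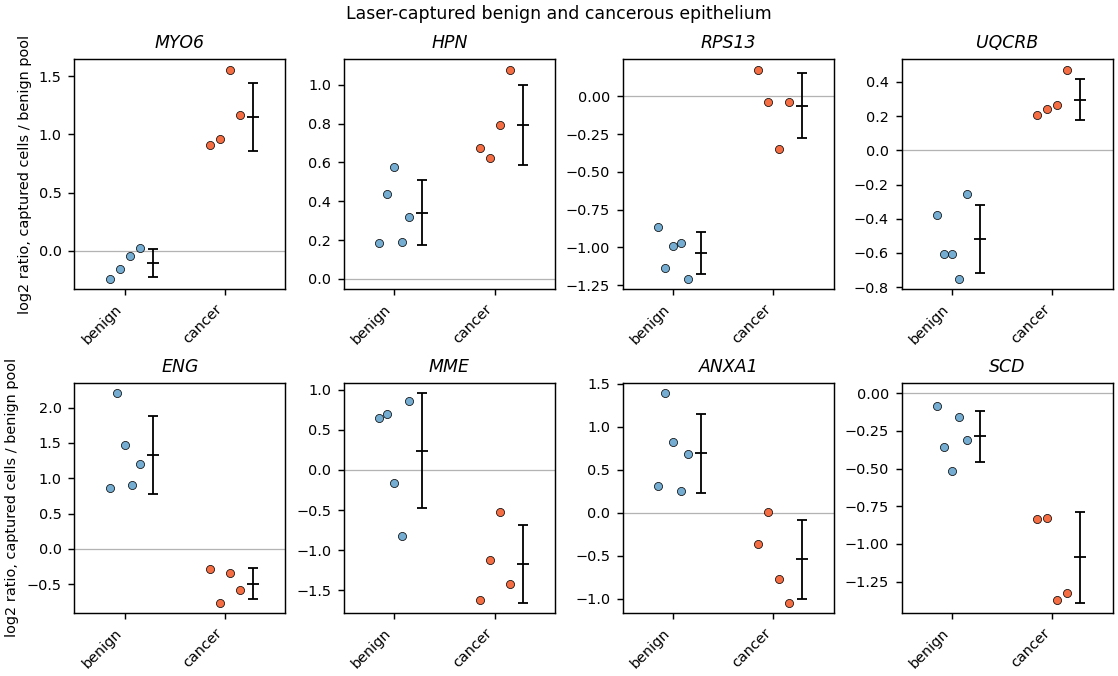
Log2 ratio over the benign pool (vertical axis) in captured benign (n = 5) and cancerous (n = 4) epithelium for MYO6, HPN, RPS13, UQCRB, ENG, MME, ANXA1 and SCD. Points are arrays and bars show the mean ± SD. MYO6 averages -0.11 over the 4 benign arrays that list it and 1.15 in cancerous epithelium.

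Captured stroma was compared with the mean of both epithelia, which tests how far the captured compartments were apart. Matrix and contractile genes rose. SPARCL1 was higher by 2.17 ± 0.20 (SE, adjusted p = 3.84e-06), at 1.57 ± 0.16 (SD, n = 2) in stroma, and COL3A1, a fibrillar collagen, by 1.91 (adjusted p = 9.15e-06). ACTA2, smooth muscle actin, was higher by 1.90 ± 0.17 (adjusted p = 3.84e-06) and ACTG2, its close paralog, by 1.99. CDH1, E-cadherin of epithelial junctions, fell by 0.91 (adjusted p = 0.00159), and PMEPA1, an androgen-induced membrane protein, by 1.17 (adjusted p = 0.00318).

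Of 2289 features, 171 changed, 98 upward and 73 downward. Of 30 named changed genes 26 had both stroma arrays beyond every epithelial array that listed the gene, and DSP, MEIS2, LMAN1 and RPL21 had 1 of 2. Not every gene was listed on all epithelial arrays, as C7 was on 3 benign and 3 cancer arrays. Other strong rises were in COL6A1 (1.80), HSPB8 (1.67), the matrix glycoprotein TNC (1.59), COL6A3 (1.499), AEBP1 (1.42) and the complement component C7 (1.39), and other strong falls in TMEM87A (-0.95), AMD1P3 (-0.95), a pseudogene of AMD1, ROM1 (-0.93), TNFSF10 (-0.91), MGST2 (-0.89), the ion cotransporter SLC12A2 (-0.89), LMAN1 (-0.87), AMD1 (-0.82) and SPINT2 (-0.81). Fibroblast and matrix genes rose in 10 of 12 cases (12 over the list alone; median 1.35, camera adjusted p = 6.01e-19), and smooth muscle genes in 6 of 6 (6 over the list alone; median 1.30, camera adjusted p = 1.73e-13), with MYH11 at 1.32 and CNN1 at 0.98. General epithelial genes fell in 4 of 10 cases (5 over the list alone; median -0.41, camera adjusted p = 0.000199), with DSP, desmoplakin, at -0.63 and GRHL2, a transcription factor of epithelia, at -0.45. These list calls were kept with an estimated correlation (7.9e-11, 6.64e-05 and 0.000198). Ribosomal protein genes fell in 2 of 17 cases (6 over the list alone), RPS19 (-0.64) and RPL21 (-0.56), with a median of -0.39 (camera adjusted p = 0.000199, adjusted p = 0.39 with an estimated correlation). Genes known to be lower in prostate cancer rose in 3 of 12 cases (3 over the list alone), CAV1 (0.81), MEIS2 (0.78) and FAM107A (0.73), with a median of 0.13 (camera adjusted p = 0.0253, adjusted p = 0.255 with an estimated correlation). GOLM1 (-0.18, adjusted p = 0.744) and FASN (-0.04, 0.947) did not pass.

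With 2 stroma arrays the count was 38 (36 higher, 2 lower) without stroma array 1 and 102 without array 2, and regions sharing a donor would make the p-values too small. Of the 30 named changed genes 13 kept their call whichever array was left out, and 17 did not. Without stroma array 1 the adjusted p was 0.656 for RPL21 (-0.35), 0.643 for AMD1 (-0.53), 0.537 for ROM1 (-0.73), 0.527 for LMAN1 (-0.49), 0.430 for AMD1P3 (-0.71), 0.384 for GRHL2 (-0.42), 0.289 for SPINT2 (-0.84), 0.232 for RPS19 (-0.57), 0.199 for FAM107A (0.72), 0.169 for CAV1 (0.75), 0.142 for MGST2 (-0.89), 0.117 for PMEPA1 (-1.02), 0.0998 for CDH1 (-0.77) and 0.0533 for TNFSF10 (-0.91). Without stroma array 2 it was 0.325 for MEIS2 (0.52), 0.303 for DSP (-0.41) and 0.106 for SLC12A2 (-0.80), and the lower-in-cancer list was not called (adjusted p = 0.102, median -0.0011). Single epithelial arrays ended calls too, as benign array 5 did for RPL21 (-0.55, adjusted p = 0.0780), ROM1 (-0.94, 0.0665), GRHL2 (-0.44, 0.0665) and AMD1 (-0.84, 0.0563), benign array 3 for RPL21 (-0.56, 0.0634), GRHL2 (-0.45, 0.0602), ROM1 (-0.92, 0.0599) and AMD1 (-0.81, 0.0592) and benign array 2 for SPINT2 (-0.79, 0.0553). ROM1, AMD1 and RPL21 also lost theirs without some of the other epithelial arrays, with adjusted p up to 0.0655, 0.0531 and 0.0636. Removing the amplification profile, chosen after seeing the data, ended those of GRHL2 (-0.33, adjusted p = 0.135) and RPL21 (-0.36, 0.177). With no filter on missing values ROM1 (adjusted p = 0.0658), RPL21 (0.0616), AMD1 (0.0614) and SPINT2 (0.0502) did not pass, nor did ROM1 with robust eBayes (0.0547) or, like RPL21 (0.0506), without centring (0.0501).

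FFPE tissue was compared with captured epithelium of the same histologies. Matrix genes were higher in FFPE tissue, with COL3A1 up by 1.501 (adjusted p = 3.39e-05), SYNPO2, an actin-binding protein of muscle, by 1.55 ± 0.17 (SE, adjusted p = 4.33e-05) and SPARCL1 by 1.48. FASN fell by 1.17 ± 0.19 (adjusted p = 0.000896) and SAT1, a polyamine acetyltransferase, by 1.10 (adjusted p = 0.00405). The metalloreductases STEAP4 (-0.98), STEAP1 (-0.82) and STEAP2 (-0.57) fell too.

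Of 2478 features, 294 changed, 167 upward and 127 downward. Compared within histology, 29 of 34 named changed genes had every FFPE array beyond the captured arrays that listed them. STEAP1, ST6GAL1, MYH11 and MEIS2 had 2 of 3 and EBP 1 of 3. Fibroblast and matrix genes rose in 9 of 12 cases (10 over the list alone; median 1.23, camera adjusted p = 6.88e-13), among them FBLN1 (1.41), VIM (1.32), FN1 (1.27) and COL6A3 (1.07). Smooth muscle genes rose in 5 of 7 cases (6 over the list alone; median 0.67, camera adjusted p = 1.65e-07), with ACTA2 at 1.18, MYH11 at 1.04 and CNN1 at 0.67. General epithelial genes fell in 5 of 11 cases (6 over the list alone; median -0.37, camera adjusted p = 0.000111), with CDH1 at -0.73, DSP at -0.70, SPINT2 at -0.65 and the protease PRSS8 at -0.58. Of 11 genes known to be higher in prostate cancer 3 fell (6 over the list alone; median -0.50, camera adjusted p = 0.00106). These calls were kept with an estimated correlation (1.52e-06, 0.0211, 0.0105 and 0.0304). Of 5 luminal genes 0 passed limma over all features and 2 fell over the list alone, with 696 features in all under an unadjusted p of 0.05 (median -0.61, camera adjusted p = 0.0328, adjusted p = 0.0446 with an estimated correlation). Sterol and fatty acid genes fell in 3 of 6 cases (5 over the list alone), with SCD at -0.66 and EBP at -0.53 (median -0.47, camera adjusted p = 0.000564, adjusted p = 0.0837 with an estimated correlation). Of 15 mitochondrial ribosomal genes 0 passed in limma, also over the list alone (median -0.16, camera adjusted p = 0.0304, adjusted p = 0.477 with an estimated correlation). Genes known to be lower in prostate cancer rose in 2 of 13 cases (2 over the list alone), CAV1 (0.87) and MEIS2 (0.70), with a median of 0.21 (camera adjusted p = 0.0328, adjusted p = 0.233 with an estimated correlation). C7 (1.33), C1S (1.30), DKK3 (1.22), MAOB (1.20) and TIMP3 (1.19) were further strong rises, and LRPAP1 (-0.83), KIF5C (-0.82), RAB3B (-0.82), PMEPA1 (-0.79), ST6GAL1 (-0.77) and VIPR1 (-0.77) further strong falls. GOLM1 (-0.73, adjusted p = 0.056) did not pass.

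Preparation and fixation differ together here, and the labels do not give the PCR rounds of the captured samples. Regions sharing a donor would make the p-values too small. The count was 147 without FFPE cancer array 1 and 92 without array 2. Without array 2 calls ended for SPINT2 (-0.59, adjusted p = 0.141), STEAP1 (-0.67, 0.139), KIF5C (-0.68, 0.102), EBP (-0.53, 0.0861), PMEPA1 (-0.71, 0.0703), STEAP2 (-0.52, 0.0686), MEIS2 (0.70, 0.0619) and RAB3B (-0.68, 0.0601), and without array 1 for ST6GAL1 (-0.73, 0.0702) and SCD (-0.57, 0.0546). SPINT2 was also not called without captured benign array 2 (-0.63, adjusted p = 0.0571) or cancer array 1 (-0.65, 0.0570). The luminal list was not called without captured benign array 2 (-0.59, adjusted p = 0.0527) or cancer array 1 (-0.46, 0.0526). The mitochondrial ribosomal list was not called without FFPE cancer array 2 (-0.12, adjusted p = 0.0819), captured benign array 1 (-0.11, 0.0718), 2 (-0.15, 0.0504) or 5 (-0.17, 0.0575), or captured cancer array 4 (-0.16, 0.0503). The lower-in-cancer list was not called without FFPE cancer array 2 (0.18, adjusted p = 0.0778), captured benign array 2 (0.22, 0.0504) or captured cancer array 3 (0.12, 0.0585) or 4 (0.16, 0.0503). Over features on every array these 3 lists had adjusted p-values of 0.0557, 0.233 and 0.0557, and with no filter on missing values the mitochondrial ribosomal list had 0.109 and SPINT2 0.0502.

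**Figure D4:**
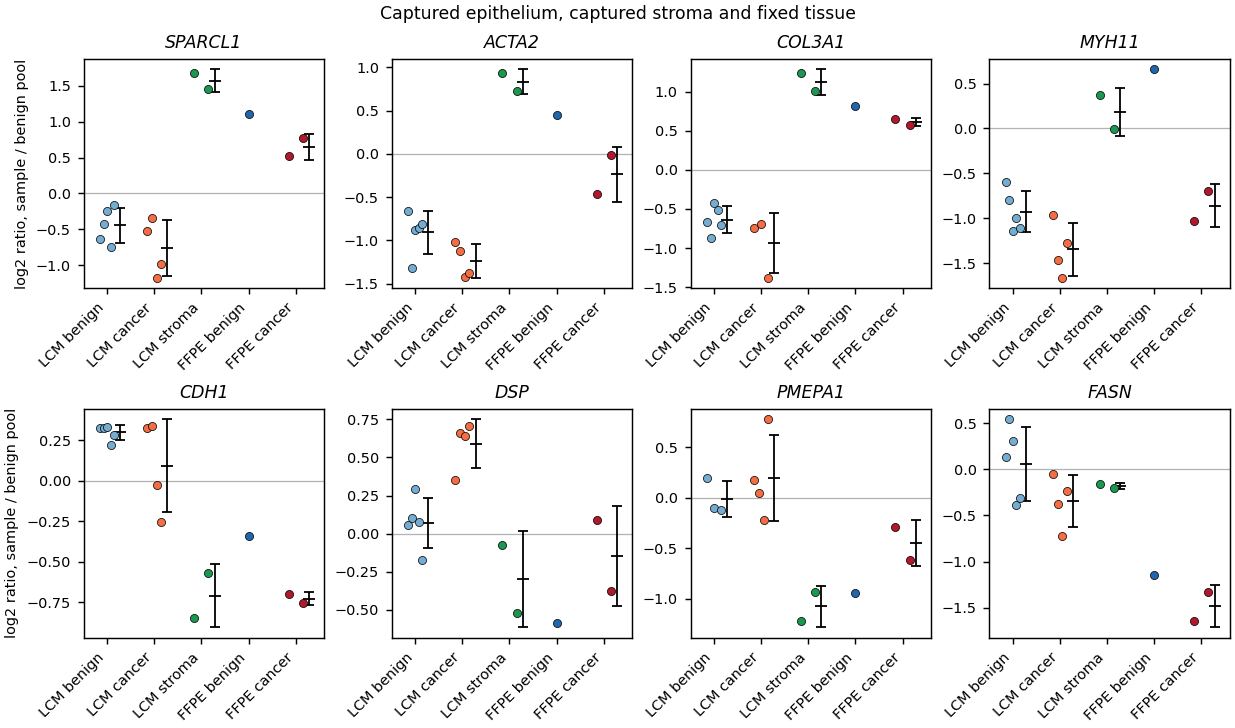
Log2 ratio over the benign pool (vertical axis) for SPARCL1, ACTA2, COL3A1, MYH11, CDH1, DSP, PMEPA1 and FASN in captured benign epithelium (n = 5), cancerous epithelium (n = 4) and stroma (n = 2) and in FFPE benign (n = 1) and cancer tissue (n = 2). Points are arrays and bars show the mean ± SD. SPARCL1 averages 1.57 in captured stroma.

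Within FFPE tissue, cancer was set against benign, with 1 benign array and so no test. Lower in both cancer arrays were LTF, lactoferrin, by a mean of -2.31, MYH11 (-1.52), SIRT4 (-1.45), ACTG2 (-1.34) and SHROOM1 (-1.26). Higher in both were ADAMTS1 (1.03), AMACR (0.95), ABCC4 (0.94), the stress-responsive transcription factor ATF3 (0.93) and SLC44A1 (0.92). GOLM1 differed by 0.76, ACTA2 by -0.69 and FASN by -0.34. Smooth muscle genes were lower in both cancer arrays for 10 of 11 members, genes known to be higher in prostate cancer were higher in both for 8 of 13, and genes known to be lower in it were lower in both for 9 of 14. Since both cancer arrays share the benign array, 2640 of all 3187 features agreed in sign, 1566 lower (49.1%) and 1074 higher (33.7%) in both. Ribosomal protein genes, which rose in 10 of 19 cases in captured cancer, were higher in both for 6 of 22 and lower in both for 10, with a median of -0.10. Over 2478 features also tested in captured cells the FFPE difference correlated with the captured difference at r = 0.474 across features, and 1639 (66.1%) had the same direction, as did 321 (86.3%) of the 372 that changed in captured epithelium. Over the 2407 of them with a value for the pool array of 2 against 4 rounds, the FFPE difference correlated with the captured difference at 0.472 and with that array's profile at 0.531, and with the captured difference given the profile at 0.327. A test of whether the difference between cancer and benign itself differed between FFPE and captured cells called 0 of 2478 features in limma, with 125 under an unadjusted p of 0.05. It rests on the single benign FFPE array, and its recovery was not simulated. The lack of calls therefore does not show that the differences were alike.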

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

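No test in this part was chosen only after the result was seen, although the genes it covered were partly chosen then. Only unamplified tissue and captured benign and cancerous epithelium were screened, where at least 4 values were present. Dixon's test compared the highest and lowest arrays with the rest. It covered each named gene and, per array, the probes listed, the SD and the slope on the amplification profile. Of 201 groups of values 8 (3.98%), all of them of genes, had an array far from the others. Chance alone gives about 1 in 20. In unamplified tissue, ADIRF stood at -3.31 on array 5, against -2.63 to -2.53 on the others. In captured benign epithelium, CD38 stood at -0.024 on array 2 (others 0.30 to 0.37), HSPB8 at -1.46 on array 2 (others -0.86 to -0.77), SLC14A1 at 0.87 on array 3 (others -0.45 to -0.12) and STEAP4 at 1.42 on array 4 (others 0.51 to 0.72). On benign array 5, COX7C stood at -0.87 (others -1.38 to -1.24) and ATP5PF at -0.69 (others -0.99 to -0.92), both subunits of mitochondrial respiration. COL6A3 stood at -0.79 on benign array 1 (others -0.60 to -0.56).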

How the results depend on the processing

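The tests chosen only after the result was seen were removal of the amplification profile and restriction to features near 0. Of 194 named gene results, 114 kept their direction and side of the threshold in every setting, 68 lost the threshold in at least 1 setting and 6 reversed in at least 1, 0 of them called. Of list medians under the alternatives, 539 were the same, 50 lost their call and 2 reversed, and of counts and array values 133 stayed and 37 moved. Array weights gave 999 changed features for unamplified against 300 ng tissue and 495 for FFPE against captured epithelium. The replicate number as a block gave 474 for 300 ng tissue, 335 for captured cancer against benign and 137 for stroma. It is not known whether the numbers pair the samples. Same-numbered arrays' deviations correlated at -0.12, 0.01 and 0.04 in tissue and at -0.16, -0.15, -0.06 and 0.04 with stroma. Between benign and cancer they correlated at 0.18, 0.02, 0.07 and 0.08, where differently numbered arrays reached 0.12. Correlations this small cannot settle whether samples are paired. Scaling to one spread gave 933 over all inputs. Features near 0 on the unamplified arrays gave 12 of 2801 for 300 ng tissue, and features near 0 in the stroma difference 256 of 1595 for captured cancer. Camera called 12 lists with an estimated correlation and 31 with the preset one. For these settings the cause was not tested.

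Leaving out 1 array gave 33 to 405 changed features for 300 ng tissue, 972 to 1377 over all inputs, 0 to 1 for the trend, 281 to 517 for captured cancer, 38 to 178 for stroma and 92 to 321 for FFPE, with fewer arrays each time. The model could not be fitted without the benign FFPE array. Reversed values were not called. In the stroma comparison FASN ran from -0.098 to 0.026, with 0.026 without benign array 2 and 0.014 without cancer array 1, and GOLM1 from -0.41 to 0.045, the latter without stroma array 2. In the trend AMACR ran from -0.018 (without 300 ng array 2) to 0.15, MYH11 from -0.0020 (without 300 ng array 2) to 0.056 and HPN from -0.024 to 0.0061 (without the 25 ng array), with 0.0010 without the 150 ng array and 0.0061 without 300 ng array 3. ACTA2 at 300 ng ran from -0.18 to 0.19 (without 300 ng array 2), with 0.076 and 0.047 without unamplified arrays 2 and 3, and was 0.074 with array weights. The oxidative phosphorylation median in captured cancer was -0.018 with the profile removed, and the lower-in-cancer median in stroma ran from -0.0011 without stroma array 2 to 0.43 without stroma array 1.

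Over features on all 9 LNCaP arrays, r with the unamplified array was 0.400 at 100 pg, 0.482 at 1 ng, 0.595 and 0.550 at 10 ng with 1 and 2 rounds, 0.529 and 0.617 at 25 ng with 1 and 2 rounds and 0.557 and 0.511 after 5 and 15 min of degradation, and for single probes it was 0.453 at 1 ng. Over features on all 6 pool arrays the SD was 0.0883, 0.111, 0.196 and 0.219 for 1 to 4 rounds, 0.286 for 2 against 4 and 0.101 from the first round. For single probes it was 0.0962, 0.146 and 0.253 for 1 to 3 rounds, 0.289 for 2 against 4 and 0.111 from the first round. Signal over background was not analysed here.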

Other observations

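The tests of the amplification profile, of ratios of opposite sign, of stroma in the benign captures and of features listed on all captured cancer arrays were chosen only after the result was seen. In FFPE tissue, immediate early genes, which respond within minutes to stress or growth factors, were higher in both cancer arrays than in the benign array for 10 of 15 members, with a median difference of 0.42, beside 1074 of all 3187 features (33.7%), and there was no test with 1 benign array, which both differences share. In captured cancer the list had a median of -0.27, but 1 of 12 rose and 1 fell, which gives no clear direction. ATF3 was at -1.25 there, which did not pass (adjusted p = 0.0620), against 0.93 in FFPE tissue. In androgen-treated LNCaP cells, all 7 measured endothelial genes were above 0 without amplification, with a median of 0.30 at percentile 100, among them ENG (0.41), VWF (0.40), A2M (0.30) and TIE1 (0.30). ENG was positive on 8 of 8 amplified arrays (0.08 to 0.87), VWF on 1 of 7 and A2M on 1 of 2. Genes known to be higher in prostate cancer had a median of 0.15 at percentile 99.8 over 24 members, mitochondrial ribosomal genes 0.10 at 99.6 over 39, translation factors -0.11 at 0.505 over 29 and general epithelial genes -0.13 at 0.76 over 19.

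AMACR was listed on 4 of 4 captured cancer arrays, at 1.29 ± 0.34 (SD), on 1 of 5 benign and on 1 of 2 stroma arrays. It was one of 87 features listed on all cancer arrays and on at most 1 benign array, which also held EMB (0.79 ± 0.41) and DUSP10 (0.79 ± 0.25), both on 0 benign arrays. Of the 126 splits of the 9 arrays 2 gave as many, the real one included, and the highest other gave 95. In the opposite direction, 60 features were listed on no cancer array and on at least 4 benign arrays, which 8 of 126 splits matched (highest other 105). The first share is under 0.05 and the second is not. The pattern was chosen after the result was seen and regions may share donors, so chance is not excluded for either direction. Since the probe filter is unrecorded, presence is not a level. Tissue array 4, unamplified tumour against an amplified reference, correlated with the unamplified mean at r = 0.858 across features with a slope of 1.03, and 75.2% of features at least 2-fold changed there were so on array 4.

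At 300 ng 268 of 315 changed ratios, and 3351 of all 5208 tested, lay nearer to 0 after amplification, and a candidate explanation is one shrinkage of all ratios. With the level taken from one pair of unamplified arrays, the slope was 0.844 to 1.05 for the other pair and 0.577 to 0.650 for the amplified arrays. Shrinkage predicted that under 20% of changed features would remain after scaling to one spread, with 50% set in advance as the bound against it; after scaling 52.1% remained (164 of 315, Wilson interval 46.6 to 57.5) and over all inputs 705 of 1429 did. Against shrinkage, which cannot turn a sign, 90 of the 315 had the opposite sign after amplification, among them MET (-1.39 to 0.41). With both means away from 0 in opposite directions at an unadjusted limma p of 0.05 there were 36 features, 29 of them changed. The highest other split of the 7 arrays gave 27, and pairs of unamplified arrays set against each other up to 15. The other splits mix amplified and unamplified arrays and can carry part of the difference, so 27 is no pure chance level. This count therefore cannot decide whether shrinkage is the whole account, and a part played by it stays open. Chance is excluded as the source of the count, since 1 of 35 splits, the real one, gave 315 and the highest other 15, and no biological explanation was tested, since all arrays hold one RNA pair.

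In captured cancer 10 of 19 ribosomal protein and 9 of 31 oxidative phosphorylation genes rose, with list calls lost with an estimated correlation (adjusted p = 0.233 and adjusted p = 0.367), and uneven amplification could contribute. Removing the profile of 2 against 4 rounds left 61.0% (SE 28.6) of the ribosomal median (0.42 to 0.26 over the 15 members with a profile value). It left -7.66% (SE 63.4) of the oxidative phosphorylation median, with a wide error. All 15 ribosomal and 26 of the 31 oxidative phosphorylation members were positive on the profile, and its slopes were higher in cancer. Removal therefore lowers both medians whatever their cause. The profile stays open as an explanation for both, and neither outcome speaks for it. The FFPE cancer arrays also lay along the profile (slopes 0.44 and 0.30, benign -0.13), yet ribosomal genes there had a median difference of -0.10, with 6 of 22 higher and 10 lower in both. Under a linear mixing model, more stroma in the benign captures is argued against as the cause for the ribosomal genes. Their difference of 0.52 exceeded the 0.12 predicted by 0.40 (SE 0.14). The model takes the stromal share from smooth muscle genes. It assumes that cancer captures hold no stroma and that regions are independent, and neither was tested. A difference between cancer and benign epithelium stays open and untested.

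In captured cancer 3 of 7 smooth muscle genes fell, with a list call lost with an estimated correlation (adjusted p = 0.367), without cancer array 3 (0.0585), without benign array 1 (0.0866) and with the amplification profile removed (0.0681, where the median stayed at -0.39 of -0.42). More stroma in the benign captures might contribute. The list, of which 1 of 30 genes is also among those known to be lower in prostate cancer, gave an estimated stromal share of 20.4 ± 7.5% (SE) in them. Fibroblast and matrix genes differed by -0.25 where that share predicts -0.43, nearer to 0 by 0.18 (SE 0.10). This is within the error allowed, so stroma and a change in the epithelium cannot be told apart with this number of arrays.

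For the other counts, over all inputs 1 of 100 splits, the real one, gave as many as 1429 changed features (highest other 28), so chance is excluded there. For FFPE against captured epithelium 1 of 90 gave as many as 294 (highest other 4). For captured cancer against benign 1 of 100 gave as many as 463, and the highest other gave 293. Splits of FFPE and captured arrays treat the regions as independent. Regions may share donors, and chance is excluded in these comparisons only if they do not. For the input trend limma's count was 0 (740 under an unadjusted p of 0.05; highest other 1), which any order reaches (100 of 100), so orders say nothing about chance there.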
